A study of Cereibacter sphaeroides 2.4.1 with 15 samples.

How the data were processed

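Cereibacter sphaeroides 2.4.1, also known as Rhodobacter sphaeroides, is a purple bacterium that can grow by photosynthesis without oxygen. Per the labels, cultures were grown in tubes under white light of 10 W/m2 while a gas of 2% CO2 and 98% N2 was bubbled through them. NaCl was added at an optical density at 600 nm of 0.4, to a final level of 0.25% (here called low salt) or 1.5% (high salt), and cells were collected 7 or 45 min later. Control cultures received no salt. Total RNA was labelled with biotin and hybridised to an Affymetrix oligonucleotide array, 1 array per sample. There were 5 control arrays, 2 arrays at low salt and 7 min, 2 at low salt and 45 min, 3 at high salt and 7 min, and 3 at high salt and 45 min, 15 in all. The labels do not say whether arrays of a group came from separate cultures. The p-values therefore measure the spread between these arrays, which may be partly technical, and the number of arrays limits the precision.

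The deposited values were probe set intensity on a linear scale, whole numbers from 18 to 31692, in a single table of 5355 probe sets. The submitters' processing notes name RMA and MAS5 for 12 arrays and no tool for 3 controls, with no version. Which tool made the values is not given in the sources used here. The median intensity of an array lay between 111 and 117, so the arrays had been brought to nearly the same median, but their quartiles differed. No detection calls were used. The arrays fell into 3 rounds of deposition, inferred from the labels and not stated in them. The first held controls 1 to 3, with no processing notes, the second held control 4 and all A and B arrays, and the third held control 5 and the C arrays of high salt. The log2 interquartile range of the first round, 2.93 to 2.99, lay inside that of the other arrays, 2.24 to 3.14, so all arrays entered a single fit by a criterion fixed before the data were examined.

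The 3 probe sets of the control gene thrC were left out, which left 5352. Values were taken as log2(intensity + 33), 33 being the 10th percentile of all values, and quantile normalized between arrays. Fold changes are on that scale, which understates the change of dim probe sets. A mean per group was fitted for each probe set with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 10 residual degrees of freedom, and 9 contrasts were tested two-sided: each treated group against control, 45 against 7 min within each NaCl level, high against low salt at each time, and the interaction of NaCl level and time. P-values were adjusted by the method of Benjamini and Hochberg over the 5352 probe sets of a contrast, with a threshold of 0.05. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

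Gene names came from the platform annotation, which gave 1 symbol to 539 probe sets (514 genes, 10.1% of probe sets) and none to 4813. No probe set had several symbols. The 4813 others entered every test and count but are not named here. All 498 distinct symbols occur in the RefSeq gene table of the assembly ASM332471v1, but no gene identifier is shared with it and the build behind the array is not given in the sources used here, so no coordinates are printed. Some symbols stand for more than 1 gene and are given with their Entrez gene identifier. Where a gene had several probe sets, the one with the highest mean value stood for it in list tests.

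Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. Of 32 lists fixed before the data were examined, 16 had at least 5 measured genes. Many of the fixed lists relied on product names, which the annotation used here did not hold, and 7 were empty. A further 12 lists, defined by symbols, were written after the counts of changed probe sets and a principal component analysis had been seen, but before any result of a single gene, which made 28 lists tested. The background was the 514 named genes. It was chosen after list results against all probe sets had been seen, and all probe sets are an added alternative. No list passed with an estimated correlation in any contrast.

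Genes were named by a rule fixed before the data were examined. For high salt against control at each time, it took the 10 largest rises and the 10 largest falls among named probe sets past the threshold with every treated array on the same side of every control array. For each other contrast it took the 5 largest of each kind. It added the 4 members with the smallest adjusted p of each list that passed camera. In contrasts with control it always added rpoE, chrR, the compatible solute list, and the kdp and trk genes where measured.

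The alternatives were median centring or no normalization between arrays in place of quantile normalization, a pseudocount of 1, leaving out the dimmest 25% of probe sets, eBayes with trend and robust settings, only the groups compared in the fit, deposit round as a block, no first-round controls, a minimum change of 1 on the log2 scale, the replicate letter as a block over the treated arrays, and leaving out each array in turn. Where 1 array was left, it was assumed to vary like the other groups. Fits without the third round, fits within the second round, treated arrays without a block, and list tests with the letter as a block were added after the data had been seen. Whether the letters pair arrays was checked from the deviations from group means. Between high salt at 7 and at 45 min, arrays of the same letter had correlations across probe sets of 0.194 (A), 0.242 (B) and 0.102 (C), all over 0.1. Arrays of different letters had -0.161 to -0.0006 there. Deviations cancel out within a group, so positive same-letter values make the different-letter ones negative on average. The latter are therefore not separate evidence, and no value expected without pairing was computed for the former. Between NaCl levels a pair of different letters reached 0.101 (high salt 7 min B with low salt 7 min A). The C arrays also shared the third round, so for them letter and round cannot be told apart. The letters were taken to pair the high-salt arrays on the same-letter correlations alone, which are weak evidence. The labels do not say what a letter stands for.

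The fit was tested on simulated data of 5352 probe sets in 10 runs. Of simulated changes of 1 on the log2 scale, it recovered 78.6% for high salt at 7 min against control, 77.2% for high salt at 45 min, 73.4% for low salt at 7 min and 73.8% for 45 against 7 min of high salt. Of simulated changes of 2 it recovered 96.5%, 96.9%, 94.1% and 95.8%. The share of false calls was 5.81%, 5.79%, 4.78% and 4.77%. A simulated list shifted by 0.5 was found in 10 of 10 runs, and 0 other lists were called. The simulated noise was independent between probe sets and held no effect of deposit round, and lists were tested with the preset correlation only. These shares therefore do not cover correlated genes or differences between rounds.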

Results

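Transcript levels were measured on 15 oligonucleotide arrays of the purple bacterium Cereibacter sphaeroides 2.4.1, grown by photosynthesis without oxygen. The groups were control (5 arrays), low salt (0.25% NaCl) for 7 min (2 arrays) and 45 min (2 arrays), and high salt (1.5% NaCl) for 7 min (3 arrays) and 45 min (3 arrays). Values are log2(intensity + 33) after quantile normalization, and changes are log2 differences with standard errors from limma. The number of arrays limits the precision. Of 5352 probe sets tested, 539 carried a gene symbol, so the named genes are a small part of the genome.

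Arrays of a group did not lie equally close together. Pearson correlations across probe sets, which are not independent replicates, were 0.957 to 0.988 between controls and 0.997 between the pair of low-salt arrays at each time. At high salt and 7 min, arrays A and B had a correlation of 0.983, but C had 0.90 with A and 0.878 with B. At 45 min the values were 0.988, 0.941 and 0.934. The first 3 principal components held 45.0%, 18.2% and 15.1% of the variance. The C arrays and control 5 made up the third round of deposition and had the narrowest log2 interquartile ranges (2.24 for C at 7 min, 2.53 for C at 45 min and 2.61 for control 5).

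**Figure D1:**
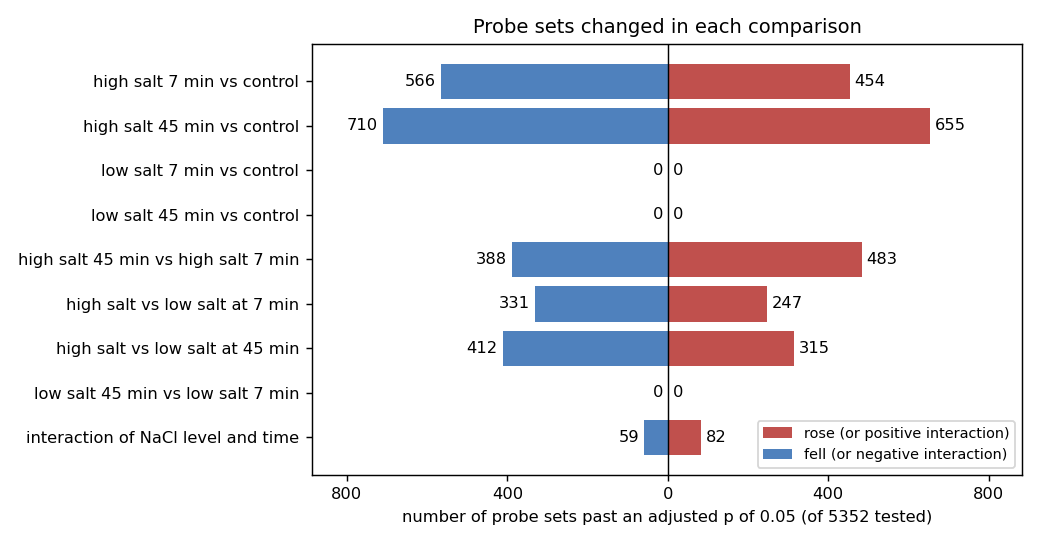
Number of probe sets that rose (red) or fell (blue) in each of the 9 comparisons, of 5352 tested, at an adjusted p under 0.05. High salt changed 1020 probe sets at 7 min and 1365 at 45 min, and low salt changed 0 at either time.

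The first comparison asked how cells responded within minutes of a strong salt addition. Single regulatory genes rose, among them rpoE, which encodes a sigma factor of the extracytoplasmic type, and ihfA, which encodes a subunit of the DNA-bending integration host factor. Many genes of the flagellum, of purine and pyrimidine synthesis and of the aminoacyl-tRNA synthetases fell, processes that cells use for swimming and for growth. Of the genes for compatible solutes, the small molecules that balance outside salt, only proX passed. High salt for 7 min against control changed 1020 probe sets, of which 454 rose and 566 fell, and 371 of them changed by at least 1. Among genes with a symbol, 26 rose and 106 fell.

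Among named genes the largest rise at 7 min was of repA (gene 4796457), which encodes a plasmid replication initiator, by 2.66 ± 0.54 (6.33-fold, adjusted p = 0.00524). The mismatch repair gene mutL (3720854) rose by 2.26 ± 0.42 (adjusted p = 0.00311), from 8.01 ± 0.07 (SD, n = 5) to 10.27 ± 1.37 (SD, n = 3). The gene rpoE (3720372) rose by 1.85 ± 0.37 (3.60-fold, adjusted p = 0.00470), from 6.38 ± 0.10 to 8.22 ± 1.18. The rise of ihfA (3720284) was 1.82 ± 0.20 (3.52-fold, adjusted p = 0.000145). Further rises were of cbbR (3718200), a regulator of carbon fixation genes, by 1.84 ± 0.45, cysS (3720452) by 1.50 ± 0.28, ugpB (3721890) by 1.23 ± 0.22, xylF (3718173) by 1.10 ± 0.21 and cysE (3720098) by 1.09 ± 0.14. In each of these genes every treated array lay above every control, as the rule for naming them required. The rises of rpoE, mutL and cbbR were larger on arrays of the second round (2.67, 3.05 and 2.70 against its control) than of the third (0.51, 0.65 and 0.18). In the RefSeq table the only gene named rpoE lies directly next to chrR, whereas on the array rpoE is probe set 3624 and chrR (3720852) probe set 1993, with gene identifiers that are not adjacent either. Whether the array's rpoE is the neighbour of chrR was therefore left open, and chrR did not pass (-0.04, adjusted p = 0.956).

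Of 19 flagellum genes, 9 fell and 0 rose at 7 min (median -1.15, camera adjusted p = 0.00354, adjusted p = 0.924 with an estimated correlation), and 15 fell when adjusted over the list alone. The largest falls in the list were of the rod genes flgB (3719952), by -2.18 ± 0.38, and flgG (3719947), by -1.72 ± 0.40, and of fliE (3719959), by -1.65 ± 0.23. The median was -1.35 within the second round and -0.43 within the third. Of 16 purine and pyrimidine synthesis genes, 9 fell, among them purQ (-1.58 ± 0.29), pyrC (-1.06 ± 0.13) and guaA (-1.28), and 11 fell when adjusted over the list alone (median -0.82, adjusted p = 0.00354, adjusted p = 0.924 with an estimated correlation). Of 15 aminoacyl-tRNA synthetase genes, 8 fell, such as metG (adjusted p = 0.000217), trpS (-0.86) and serS (-0.78), while cysS rose; adjusted over the list alone 13 fell and 1 rose (median -0.63, adjusted p = 0.0237, adjusted p = 0.924 with an estimated correlation). With deposit round as a block that list had an adjusted p of 0.105. Its median was -0.83 within the second round and -0.03 within the third, though metG (-0.73), trpS (-0.66) and serS (-0.64) fell within the third. The purine and pyrimidine median was -0.997 within the second round and -0.205 within the third. Of the genes of histidine utilization, by which histidine is broken down for carbon and nitrogen, hutC rose by 0.64 ± 0.12, hutI by 0.79 ± 0.15 and hutH (3722088) by 0.35 ± 0.11, while hutU did not pass (0.12), and adjusted over the list alone 3 of 5 genes rose (median 0.35, adjusted p = 0.00354, adjusted p = 0.113 with an estimated correlation). These hut genes were dim: on the controls hutC lay at 5.91 to 6.16 and hutH (3722088) at 6.16 to 6.21. At 7 min of high salt hutH (3722088) and hutU were highest on array C (6.79 and 6.65). The list median was 0.21 within the second round and 0.54 within the third. Single genes outside these lists fell too, among them the ribosomal protein genes rpsG (3718917) by -1.93 ± 0.25 and rpsL (3718916) by -1.61 ± 0.16, and alr by -1.34 ± 0.13.

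The ribosomal protein list at 7 min had a median of -0.49 within the second round but 0.09 within the third. As a whole it did not pass (9 of 45 genes fell, median -0.19, adjusted p = 0.790). Nor did heat shock chaperones and proteases (1 of 11 fell, median -0.04, opposite in sign to the test), light-harvesting and reaction centre proteins (0 of 7 called, median 0.11) or nitrogen fixation (0 of 11 called, median -0.03, and 0.01 with median centring). Bacteriochlorophyll and carotenoid synthesis had a median of -0.14, opposite in sign to its test, and 2 of 15 genes fell. The compatible solute list did not pass (median 0.08, adjusted p = 0.0811). Of its 6 genes, also adjusted over the list alone, only 1 was called: proX (3719651) rose by 0.51 ± 0.13 (adjusted p = 0.0140), and otsA (3720777), of trehalose synthesis, did not pass (0.69 ± 0.35, adjusted p = 0.205). The call of proX was lost with deposit round as a block (adjusted p = 0.0807), with median centring (0.102) and with no normalization (0.0892), and its change was 0.80 within the second round and 0.06 within the third. Without the third round, a fit chosen after the data had been seen, otsA rose by 1.13 (adjusted p = 0.00187) and the compatible solute list passed (median 0.25, adjusted p = 0.0228). In that fit DNA repair also passed (median 0.03, adjusted p = 0.0228). Its member mutL rose by 3.1 there, so with such a median the pass does not speak for most of its genes. Protein secretion passed with deposit round as a block (median -0.55, adjusted p = 0.0487). The potassium uptake genes kdpA (0.06), kdpB (-0.05), kdpC (-0.20) and trkA (-0.27) did not pass.

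The count at 7 min rested partly on single arrays: it was 671 without high salt B, 709 without A and 1519 without C (922 of the 1020 shared), with control arrays giving 801 to 1030. Without the 3 early controls 14 of 33 named calls were lost, with adjusted p of 0.0528 to 0.248, including those of repA, mutL, rpoE, cysS, flgB and flgG. The call of cbbR was lost without A (adjusted p = 0.0724) or B (0.0756), that of proX without A (0.0619) or B (0.0696), and that of hutH without A (0.0679), C (0.104) or any 1 control (0.0586 to 0.0737). That of hutH was also lost with median centring (0.0692) and no normalization (0.0732). With only the groups compared, hutH (0.0714), cbbR (0.0705), proX (0.0597) and flgG (0.0582) lost their calls, and within the second round hutH (0.111) and hutC (0.0765) lost theirs.

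**Figure D2:**
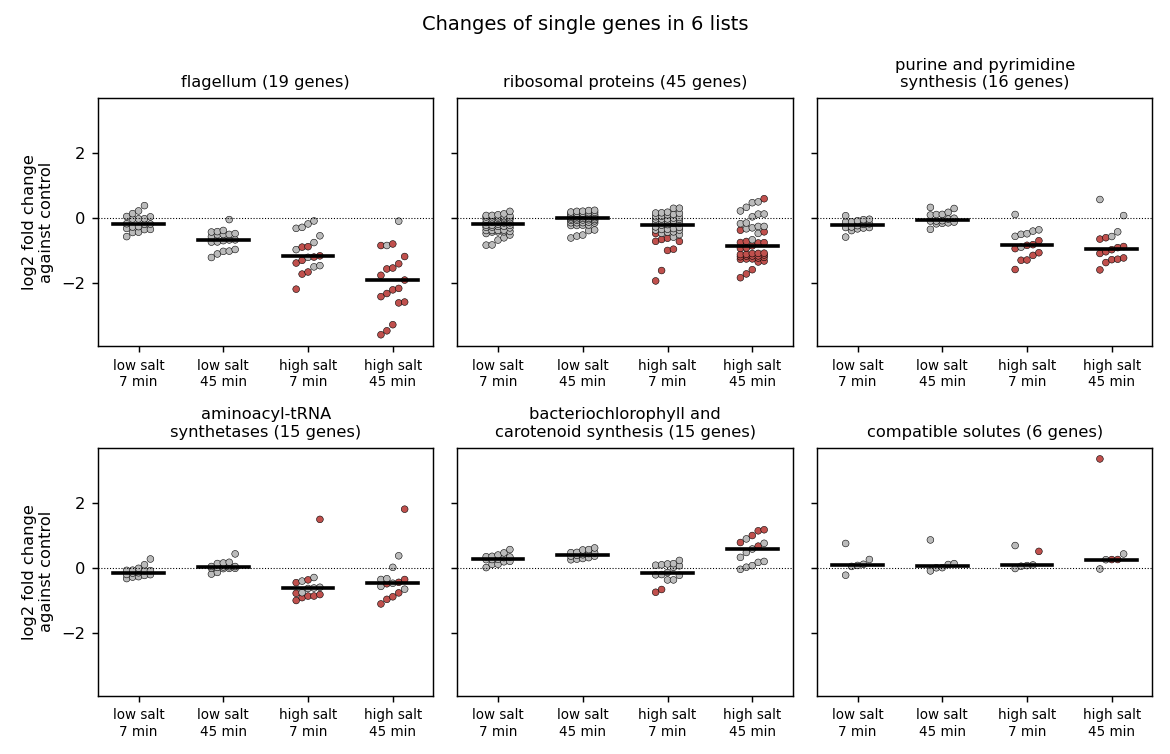
Log2 fold change against control of each gene of 6 lists at low salt 7 and 45 min and high salt 7 and 45 min; red points passed an adjusted p of 0.05 and black bars are medians. The flagellum median went from -1.15 at 7 min to -1.90 at 45 min of high salt, and the ribosomal protein median from -0.19 to -0.85. The ribosomal medians at these times were -0.49 and -0.87 within the second round and 0.09 and -0.68 within the third.

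The second comparison asked what state the cells had reached after 45 min of high salt. The gene otsA, which makes the precursor of the compatible solute trehalose, had the largest rise of any named gene. The flagellum, a costly organelle, fell in almost every gene measured, and most genes of ribosomal proteins and of purine and pyrimidine synthesis, which serve growth, fell. Some genes of bacteriochlorophyll and carotenoid synthesis, which make the pigments of photosynthesis, rose, bchE and bchJ among them. High salt for 45 min against control changed 1365 probe sets, of which 655 rose and 710 fell, and 622 of them changed by at least 1. Among genes with a symbol, 62 rose and 139 fell.

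The rise of otsA was 3.36 ± 0.35 (10.2-fold, adjusted p = 3.94e-05), from 7.26 ± 0.42 (SD, n = 5) to 10.62 ± 0.17 (SD, n = 3), and was 2.94 within the second round and 4.12 within the third. Next came repA (4796457) at 2.50 ± 0.54 and mutL at 2.32 ± 0.42. The gene cysE (3721647), for a serine acetyltransferase of cysteine synthesis, rose by 1.89 ± 0.26 (adjusted p = 0.00022), and cysS by 1.81 ± 0.28. The sigma factor gene rpoE stayed up at 1.84 ± 0.37 (adjusted p = 0.00295), with 2.15 and 1.51 within the rounds. The isoprenoid gene dxr (3720438) rose by 1.65 ± 0.21, dapF by 1.38 ± 0.18 and cbbR by 1.66 ± 0.45. Of the compatible solute genes, betA (0.26 ± 0.09, adjusted p = 0.0417) and betB (0.26, adjusted p = 0.0427), which turn choline into glycine betaine, also rose. Adjusted over the list alone, 3 of 6 genes rose (median 0.26, adjusted p = 0.0238, adjusted p = 0.620 with an estimated correlation). The list had an adjusted p of 0.0852 without the third round. With deposit round as a block it had 0.0700 and the call of betB was lost (0.170). The change of betB was 0.05 within the second round and 0.45 within the third. The genes betI (0.43, adjusted p = 0.103), proX (0.26), glgX (-0.03), chrR (-0.11), kdpA (0.04), kdpB (0.02), kdpC (0.20) and trkA (0.13) did not pass.

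Of 19 flagellum genes 17 fell at 45 min, and 17 adjusted over the list alone (median -1.90, adjusted p = 4.63e-07, adjusted p = 0.620 with an estimated correlation). The fall of flgG was -3.58 ± 0.40 (adjusted p = 6.10e-05), from 9.94 ± 0.45 to 6.35 ± 0.19. The stator gene motA (3719412) fell by 3.46 ± 0.44, flgB by 3.27 ± 0.38, flgC by 2.60 ± 0.26 and flgH by 2.58 ± 0.24. The switch gene fliM (3719967) had -3.07 ± 0.30 on one probe set and -0.79 on another. The list median was -2.48 within the second round and -1.05 within the third.

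Of 45 ribosomal protein genes 29 fell and 1 (rplU, 0.60) rose, and adjusted over the list alone 31 fell and 3 rose (median -0.85, adjusted p = 1.97e-05, adjusted p = 0.620 with an estimated correlation). Examples were rpmD (-1.58 ± 0.11, adjusted p = 2.59e-06), rpsB (-1.83 ± 0.21), rplR (-1.31 ± 0.12) and rpsC (-1.16 ± 0.12). Within the rounds the median was -0.87 and -0.68. Of 16 purine and pyrimidine genes 12 fell, among them guaA (-1.59 ± 0.22), purF (-1.27) and pyrC (-1.03 ± 0.13), and adjusted over the list alone 13 fell and 1 rose (median -0.93, adjusted p = 0.00811, adjusted p = 0.669 with an estimated correlation); with deposit round as a block it had an adjusted p of 0.0614. Of 15 pigment synthesis genes 5 rose, also 5 adjusted over the list alone (median 0.58, adjusted p = 0.00104, adjusted p = 0.654 with an estimated correlation). They included bchE, for the cyclase used without oxygen (1.18 ± 0.11, adjusted p = 1.81e-05), bchJ (1.14 ± 0.20), crtD (0.78 ± 0.17) and crtB (1.00 ± 0.27). The pigment median was 0.78 within the second round and 0.03 within the third. The light-harvesting and reaction centre proteins themselves did not pass (0 of 7, median 0.22, adjusted p = 0.291), nor did heat shock genes (1 rose and 2 fell of 11, median -0.27) or DNA repair (4 of 16 rose, median 0.12, adjusted p = 0.0557). In potassium, sodium and chloride transport, mscL rose by 0.74 and nhaD fell by 1.36.

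The count at 45 min was 1167 to 1368 when 1 array was left out. Without the 3 early controls 6 of 35 named calls were lost (cbbR, fliN, fliK, crtB, betA and betB, adjusted p of 0.0755 to 0.291). The call of cbbR was lost without high salt A (0.0588), that of crtB without A (0.0805) or B (0.0745) and with only the groups compared (0.0573), and those of betA and betB without most single arrays (0.0511 to 0.156).

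**Figure D3:**
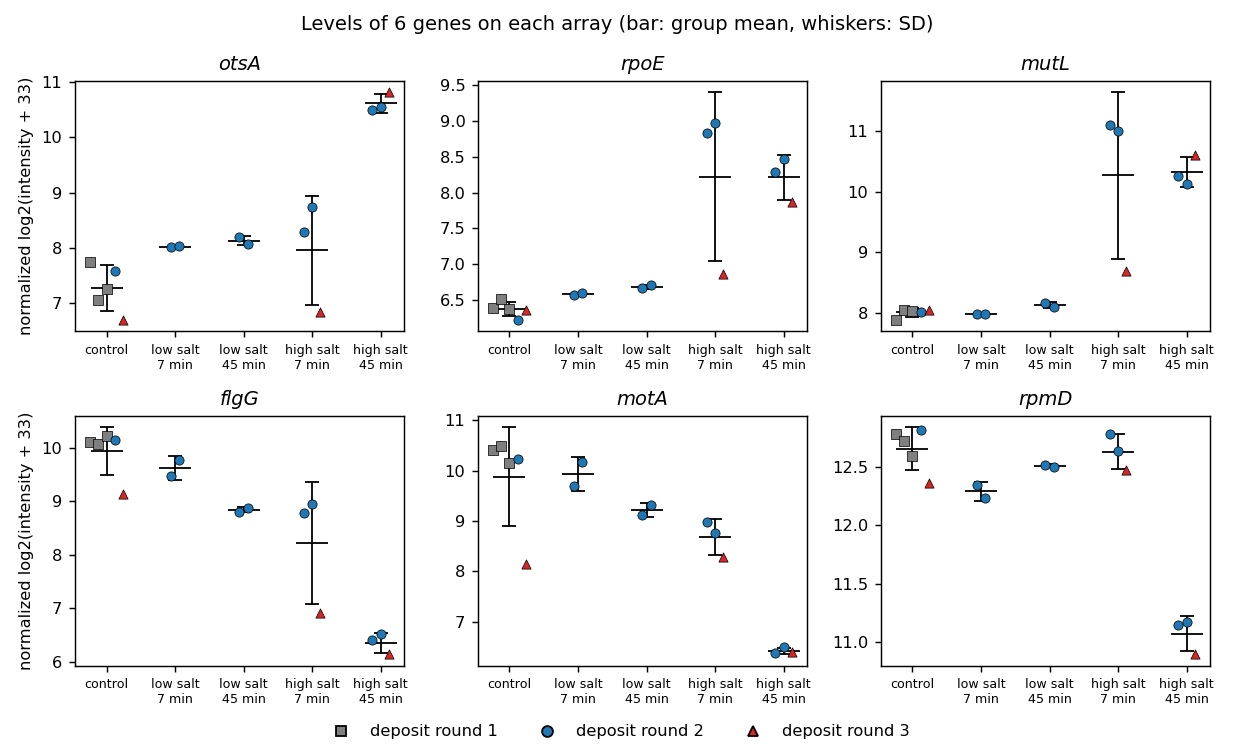
Normalized log2(intensity + 33) of 6 genes on each array by group; squares, circles and triangles are rounds 1, 2 and 3 of deposition, bars are means and whiskers SD. In otsA the high-salt 45 min arrays average 10.62 against 7.26 in controls, and in flgG 6.35 against 9.94.

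The third comparison asked how the response to high salt moved between 7 and 45 min. The trehalose gene otsA rose over this time, while many ribosomal protein genes and some flagellum genes fell. The genes pstA and pstB, of the phosphate transporter, and edd, of the Entner-Doudoroff route of sugar breakdown, rose. So did appA, an antirepressor of photosynthesis genes, and some pigment synthesis genes. Between these times 871 probe sets changed, of which 483 rose and 388 fell. That fit ignored the replicate letters. With the letter as a block over the treated arrays 949 changed, 684 of them shared with the 871. Among named genes the largest rises were of otsA (2.67 ± 0.39, 6.34-fold, adjusted p = 0.000789), edd (1.97 ± 0.34), pstA (1.95 ± 0.31), pstB (1.91 ± 0.16, adjusted p = 1.15e-05) and appA (1.78 ± 0.35). The largest falls of named genes were of motA (-2.26 ± 0.49), xylF (-2.26 ± 0.23), the chaperonin gene groEL (3719842; -2.05 ± 0.32), gltB, for glutamate synthase (-1.99 ± 0.17), and flgG (-1.87 ± 0.45). In these genes every array at 45 min lay on the same side of every array at 7 min, as the rule for naming them required.

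Between the times 22 of 45 ribosomal protein genes fell, with rpmD at -1.56 ± 0.13 and rplR at -1.48, and 6 rose, among them rpsG and rpsL, which had fallen at 7 min. Adjusted over the list alone 25 fell and 7 rose (median -0.75, adjusted p = 0.000239, adjusted p = 0.735 with an estimated correlation). The rounds differed in how far this list had already fallen by 7 min. Against control its median then was -0.49 within the second round and 0.09 within the third. Of the flagellum genes 6 fell, such as flgH (-1.70) and flgC (-1.31), and 10 adjusted over the list alone (median -0.76, adjusted p = 0.000249, adjusted p = 0.735 with an estimated correlation). Of the pigment genes 5 rose, among them bchI (1.42 ± 0.24), bchJ (1.37) and bchE (1.04), and 7 adjusted over the list alone (median 0.68, adjusted p = 0.0112, adjusted p = 0.735 with an estimated correlation). In a fit of these 6 arrays alone 242 probe sets changed, and pstA, appA, groEL, flgG, bchI and bchB lost their calls (adjusted p of 0.0581 to 0.182). Leaving out 1 array gave 627 to 1175 changed probe sets (1175 without high salt 7 min C). The call of flgG was lost without 7 min A (0.0523) and that of bchB without 7 min A (0.0588), 45 min A (0.0756) or 45 min B (0.0723).

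The changes at the 2 times of high salt overlapped. Both times shared 221 probe sets that rose (55.6 expected for independent contrasts) and 283 that fell (75.1 expected), and 33 went opposite ways. The 2 contrasts use the same controls and so are not independent. Simulated unchanged groups with the same controls shared 0, but unchanged groups give few calls at all. That 0 therefore does not measure what shared controls add to the overlap. The correlation of the changes across genes, which are not independent replicates, was 0.605, against 0.378 in simulated unchanged groups, and 0.492 to 0.606 when the controls were split between the times. Between high and low salt it was 0.201 at 7 min (0.322 simulated, -0.031 to 0.233 with split controls) and 0.488 at 45 min (0.320 simulated, 0.168 to 0.504 with split controls). Between the times of low salt it was 0.685 (0.282 simulated, 0.228 to 0.508 with split controls). The simulated groups shared only the controls, with no pairing by letter and no shared round, so the simulated values may be too low.

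The fourth comparison asked whether a mild salt addition had an effect within 7 min. All low-salt arrays were in the second round, which held 1 control. No single gene passed, neither otsA, of trehalose synthesis, nor rpoE, for a sigma factor. The lists of ribosomal proteins, parts of the translation machinery, and of pigment synthesis passed only with a preset correlation. Low salt for 7 min against control changed 0 probe sets with limma, and 253 had an unadjusted p under 0.05 where 267.6 were expected. In fits chosen after the data had been seen, 128 changed without the third round (87 rose and 41 fell) and 218 within the second. The changes of otsA (0.75 ± 0.40) and rpoE (0.21 ± 0.42) did not pass, nor did those of bchE (0.40 ± 0.12) and rpsT (-0.83 ± 0.26), both with an adjusted p of 0.759. Pigment synthesis had a median of 0.27 (adjusted p = 0.000573, adjusted p = 0.833 with an estimated correlation) and ribosomal proteins -0.18 (adjusted p = 0.000573, adjusted p = 0.833 with an estimated correlation), each with 0 genes called, also when adjusted over the list alone. With deposit round as a block the pigment median was -0.07 (adjusted p = 0.749) and the ribosomal median -0.09 (adjusted p = 0.270). The flagellum list did not pass (median -0.18, adjusted p = 0.354), but did so with that block (-0.26, adjusted p = 0.0381) and without the third round (-0.38, adjusted p = 2.02e-05). Cobalamin synthesis also passed with that block (-0.38, adjusted p = 0.0181), and purine and pyrimidine synthesis without the third round (-0.25, adjusted p = 0.0486).

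The fifth comparison asked the same after 45 min of low salt. No single gene passed, neither the trehalose gene otsA nor flagellum genes such as flgH and flgA. The lists of the flagellum, of pigment synthesis and of light-harvesting proteins passed only with a preset correlation. Low salt for 45 min against control changed 0 probe sets with limma, and 179 had an unadjusted p under 0.05. The count was 8 without control 5 and 0 without any other single array. It was 90 without the third round (28 rose and 62 fell) and 211 within the second. The flagellum median was -0.66 (adjusted p = 1.13e-17, adjusted p = 0.408 with an estimated correlation), with 0 genes called and 3 falling when adjusted over the list alone. All 19 flagellum genes had a negative change. Their median was -0.91 without the third round and -1.05 within the second, the latter against 1 control. None of flgH (-1.02 ± 0.28, adjusted p = 0.721), flgA (-0.66 ± 0.19), otsA (0.86 ± 0.40) and rpoE (0.31 ± 0.42) passed. Pigment synthesis had a median of 0.41 (adjusted p = 4.08e-06, adjusted p = 0.714 with an estimated correlation) and light-harvesting and reaction centre proteins 0.18 (adjusted p = 0.0347, adjusted p = 0.714 with an estimated correlation). With deposit round as a block the pigment median was 0.11 (adjusted p = 0.758) and the other list had an adjusted p of 0.798.

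Between 45 and 7 min of low salt, a comparison of 2 arrays with 2, no single gene passed, flagellum genes such as flhA and flgA included, and lists passed only with a preset correlation. Limma called 0 probe sets, with 66 at an unadjusted p under 0.05, and 36 without the third round. The flagellum median was -0.57 (adjusted p = 7.68e-19, adjusted p = 0.341 with an estimated correlation) and the ribosomal median 0.16 (adjusted p = 0.000355, adjusted p = 0.792 with an estimated correlation). Cobalamin synthesis (0.20, adjusted p = 0.00188), purine and pyrimidine synthesis (0.20, adjusted p = 0.0276) and aminoacyl-tRNA synthetases (0.14, adjusted p = 0.0256) also passed, each with an adjusted p = 0.792 with an estimated correlation. With the replicate letter as a block the last 2 of these lists had an adjusted p of 0.215.

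High against low salt at 7 min asked which early changes depended on the NaCl level. The genes repA, mutL, ihfA, rpoE and ugpB, the last for a glycerol-3-phosphate binding protein, were higher at high salt. The ribosomal protein genes rpsG and rpsL and the flagellum genes flgB, fliE and fliP were lower, and hutI and hutC, of histidine breakdown, were higher. The comparison gave 578 changed probe sets, of which 247 rose and 331 fell with the NaCl level. This division depended on the scaling: 271 rose and 547 fell with median centring, and 267 rose and 565 fell with no normalization. The differences were 2.61 ± 0.68 for repA (4796457), 2.29 ± 0.53 for mutL, 1.72 ± 0.25 for ihfA (adjusted p = 0.00178), 1.63 ± 0.46 for rpoE (adjusted p = 0.0423) and 1.61 ± 0.28 for ugpB. Those of rpsG (-1.82 ± 0.31), flgB (-1.62 ± 0.48), hisF (-1.55 ± 0.29), cysT (-1.51 ± 0.41) and rpsL (-1.46 ± 0.20) were the largest falls of named genes. Of 19 flagellum genes 3 fell, and 6 adjusted over the list alone (median -0.95, adjusted p = 0.0399, adjusted p = 0.898 with an estimated correlation; 0.114 with deposit round as a block and 0.113 without the third round). Of the histidine utilization genes 2, hutI (0.80) and hutC (0.58), rose, and 3 adjusted over the list alone (median 0.33, adjusted p = 0.0302, adjusted p = 0.205 with an estimated correlation; 0.0516 without the third round). The count fell to 90 without low salt A and 109 without low salt B and was 1114 without high salt C. It was 34 in a fit of these 5 arrays alone, where all 14 named calls were lost (adjusted p of 0.0690 to 0.342). Without the 3 early controls 8 of them were lost (0.0599 to 0.111). With the replicate letter as a block over the treated arrays repA, mutL and hutC lost their calls (0.0670 to 0.170). Of the 14, 12 were lost without low salt A (adjusted p of 0.0546 to 0.217) and 12 without B (0.0502 to 0.311), ihfA and rpsL being kept there. Without high salt A 6 were lost (0.0501 to 0.122), without B 6 (0.0517 to 0.121), and without C that of flgB (0.0694).

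High against low salt at 45 min asked the same of the later state. The trehalose gene otsA, with repA, mutL, cysE and cysS, was higher at high salt. Many ribosomal protein genes and some flagellum, purine and pyrimidine genes were lower, from lists that also fell against control. The comparison gave 727 changed probe sets, 315 rising and 412 falling with the NaCl level. Among named genes the largest difference was that of otsA, 2.49 ± 0.44 (5.63-fold, adjusted p = 0.00333), followed by repA (4796457; 2.48 ± 0.68), mutL (2.20 ± 0.53), cysE (3721647; 1.92 ± 0.32) and cysS (1.66 ± 0.35). The largest falls of named genes were of motA (-2.80 ± 0.55), flgG (-2.49 ± 0.50), fliM (-2.16 ± 0.38), flgB (-2.07 ± 0.48) and fliE (-1.99 ± 0.29). Of the ribosomal protein genes 25 fell, with rpmD at -1.44 ± 0.14, and 2 rose, and 29 fell and 2 rose adjusted over the list alone (median -0.79, adjusted p = 4.30e-05, adjusted p = 0.633 with an estimated correlation). Of the flagellum genes 8 fell, and 12 adjusted over the list alone (median -1.25, adjusted p = 0.000763, adjusted p = 0.633 with an estimated correlation). Of the purine and pyrimidine genes 6 fell, among them guaA (-1.89 ± 0.27), and 10 adjusted over the list alone (median -0.89, adjusted p = 0.0103, adjusted p = 0.633 with an estimated correlation). Of the compatible solute genes otsA alone rose, also adjusted over the list alone (median 0.20, adjusted p = 0.0373, adjusted p = 0.633 with an estimated correlation; 0.127 with the replicate letter and 0.0512 with deposit round as a block, 0.130 without the third round). Pigment synthesis did not pass (median 0.11, adjusted p = 0.0807), but did so with deposit round as a block (median 0.35, adjusted p = 0.00403), with the letter as a block (0.40, adjusted p = 0.000283) and without the third round (0.52, adjusted p = 2.75e-05). With the letter as a block repA (0.170), mutL (0.0640), cysS (0.0669) and purF (0.0597) lost their calls. Without the 3 early controls repA and mutL lost theirs (0.0565 to 0.0788), and with only the groups compared repA did (0.0869). The count was 229 without low salt A, 244 without low salt B, and 594 to 630 without 1 high-salt array. Of 20 named calls 9 were lost without low salt A (adjusted p of 0.0508 to 0.160) and 9 without B (0.0625 to 0.181), among them those of repA, mutL and flgG, and that of repA also without high salt C (0.0864).

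The last comparison tested whether the change from 7 to 45 min differed between the NaCl levels. The phosphate uptake genes pstA and pstB, appA and the pigment gene bchE rose between the times at high salt, and some ribosomal protein genes, the elongation factor gene tsf and gltB, of nitrogen assimilation, fell. At low salt none of these passed between the times, and several leaned the other way, such as pstB (-0.34), pstA (-0.26), gltB (0.32), rpsP (0.53) and tsf (0.18). This interaction was found for 141 probe sets, 82 positive and 59 negative. The differences of the time changes were 2.25 ± 0.25 for pstB (adjusted p = 0.000625), 2.22 ± 0.49 for pstA, and 2.19 ± 0.52, 1.67 ± 0.38 and 1.47 ± 0.19 for 3 probe sets of appA. They were -2.31 ± 0.27 for gltB (adjusted p = 0.000871), -2.23 ± 0.38 for rpsP, -1.80 ± 0.37 for rpsB, -1.79 ± 0.36 for tsf and -1.78 ± 0.20 for rpmD. Of the ribosomal protein genes 9 were negative, and 22 negative and 5 positive adjusted over the list alone (median -0.91, adjusted p = 9.94e-07, adjusted p = 0.944 with an estimated correlation). Of the pigment genes bchE passed (1.08 ± 0.19), and 3 adjusted over the list alone (median 0.67, adjusted p = 0.0465, adjusted p = 0.944 with an estimated correlation). Of the 13 named calls 5 were lost without the 3 early controls (adjusted p of 0.0644 to 0.131), 6 with only the groups compared (0.0568 to 0.168) and 5 with the letter as a block (0.0685 to 0.173). The count was 32 and 35 without low salt 7 min A and B, 41 and 34 without low salt 45 min A and B, 387 without high salt 7 min C and 233 without high salt 45 min C. Of the named calls 8 were lost without low salt 7 min A (adjusted p of 0.0600 to 0.211), 7 without 7 min B (0.0583 to 0.150), 4 without 45 min A (0.0915 to 0.129) and 8 without 45 min B (0.0734 to 0.221). Those of pstB, gltB, rpmD, rplR and 1 probe set of appA were kept without each of these, and without 1 high-salt array only calls of appA were lost (0.0544 without 7 min A, 0.0671 without 45 min C, 0.0646 to 0.0805 without 45 min A or B).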

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

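The tests on low salt, their division into rises and falls, the fits without the third round and the flagellum median of control 5 were chosen after results had been seen, and the other tests before. Among 108 named probe sets and array measures, 11 had 1 control far from the other 4, and in 9 of these it was control 5. Chance alone puts about 1 in 20 groups there. The gap to the nearest control over the whole range was 0.834 for the log2 interquartile range (2.61 in control 5, 2.93 to 2.99 in the others) and 0.962 for the mean intensity of the thrC control probe sets (30 against 21.3 to 21.7). The C arrays of high salt, in the same round, had 43 at 7 min and 38 at 45 min. In the flagellum genes flgG, flgC, motA and fliK it was 0.858, 0.792, 0.851 and 0.852. In flgG control 5 had 9.13 against 10.07 to 10.22, and in motA 8.14 against 10.14 to 10.49. In dxr, bchZ and bchC it was 0.716, 0.733 and 0.761, control 5 being lowest. Control 1 was low in mutL (0.769; 7.89 against 8.02 to 8.06) and control 2 in pstA (0.728; 7.44 against 7.86 to 8.01). Over the 19 flagellum genes, which include flgG, flgC, motA and fliK, control 5 had a median difference of -1.18 from the other controls and was lower in 18 genes. The fall of the flagellum list at high salt was also present within the second round, which does not hold control 5.

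The change from 7 to 45 min differed between high and low salt for 141 probe sets by the interaction test. Of these, 15 positive and 13 negative probe sets carried a symbol, and not all of them are listed here. Among the positive ones the naming rule picked pstB (2.25), pstA (2.22), appA (2.19, 1.67 and 1.47 on 3 probe sets) and bchE (1.08). Among the negative ones it picked gltB (-2.31), rpsP (-2.23), rpsB (-1.80), tsf (-1.79), rpmD (-1.78), rplR (-1.70) and rpsE (-1.53).

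The grouping behind the counts was tested by dividing the same arrays in other ways. For high salt 7 min against control, 1 of 56 splits, the real one, gave as many changed probe sets (1020, highest other 54), and for 45 min 1 of 56 (1365, highest other 7). This argues against chance only if arrays of different rounds can be exchanged. Splits that mix treated and control arrays also widen the spread within groups, which lowers their counts. Only 6 of the splits take as many arrays from each round as the real one (highest other 54 at 7 min and 0 at 45 min), too few for a share under 0.05 within rounds. Between 45 and 7 min of high salt, 1 of 10 splits gave as many (871, highest other 235), and 10 splits are too few for a share under 0.05. The splits that part as many letters as the real one gave 235, 0 and 0.

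The C arrays of high salt lay apart from A and B, most at 7 min. A compression left alike on all arrays of the third round after quantile normalization was argued against, since the slopes differed between the times. The changes of C against control 5 had a slope on those of A and B of 0.916 (0.886 to 0.948) at 45 min and of 0.337 (0.303 to 0.372) at 7 min. Normalization had already evened out the range of each array, so compression in the deposited values was not tested. The probe sets used were those changed without the third round, so they were chosen on A and B. A wrong label on the C array of 7 min was argued against, since its changes correlated with those of its own group more than with any other by 0.248 (0.217 to 0.279). The ranges of the slopes and of this difference are 95% ranges over resampled probe sets, which are not independent. They hold no spread between arrays or cultures. Different growth or handling of the third round's cultures and a difference in array processing cannot be told apart, because the round holds 1 array of each group. The thrC values and the lowest intensities (21, 24 and 22 against 18) were raised on all its arrays, which points to array processing but does not exclude a difference between cultures. A biological difference between the cultures was not tested.

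The fall of ribosomal protein genes at 45 min of high salt (median -0.85) was weighed against a bias of bright probe sets. Probe sets matched on mean value had a median change of 0.040 (-0.236 to 0.211), and 0 of 1000 draws were as low as the list. Without the third round the median was -0.89. Both explanations were argued against. A biological response to high salt stays open and was not tested.

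At low salt, no probe set passed with all arrays, with 253 at 7 min and 179 at 45 min at an unadjusted p under 0.05 with limma. Without the third round 128 passed at 7 min and 90 at 45 min. In that fit all low-salt arrays were in the second round, while most controls were in the first. A difference between the first and second rounds could therefore also give such calls. With all arrays and deposit round as a block, 0 passed at either time. Whether spread added by the third round was the reason for the count of 0 thus cannot be told. Of the probe sets that rose at high salt 45 min, 68.0 to 87.6% also rose at low salt when separate controls were used, at least 15.8 points above all probe sets, which at 45 min argues against shared controls as the whole cause. Separate controls leave the deposit round shared, since all low-salt arrays and the A and B arrays of high salt were in the second round, so a shift of that round stays open. For those that fell the lowest excess was 1.10 points (48.9 to 72.4% of the same sign), so a small response and the shared controls cannot be told apart there. At 7 min the share was 48.0 to 78.0% for rises (lowest excess -2.77 points) and 44.7 to 68.0% for falls (-7.77 points), so a shared direction beyond the controls was not shown.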

How the results depend on the processing

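The fits without the third round, within the second round, of treated arrays without a block, and the list tests with the letter as a block were chosen after the data had been seen. The number of arrays limits all results. Of 135 named results past the threshold, 76 kept direction and call under every alternative and 0 reversed. The uncalled change of glgX at high salt 7 min (0.07) reversed to -0.19 without the third round and -0.30 within the second. The other counts stayed within 1.5 times their main value; the cause of the following shifts was not tested, apart from the stricter threshold and the loss of arrays. Without the 3 early controls the counts were 314 (high salt 7 min), 737 (high salt 45 min), 367 (high against low at 7 min) and 56 (interaction). With only the groups compared they were 640 (high salt 7 min), 8 and 1 (low salt 7 and 45 min), 242 (45 against 7 min of high salt), 34 (high against low at 7 min) and 58 (interaction). With a change of at least 1 they were 371, 622, 373, 290 and 409 for high salt 7 min, 45 min, their difference, and high against low at 7 and 45 min. With deposit round as a block the interaction count was 314. Without the third round they were 2206, 2075, 128, 90, 1761, 1858, 1534, 36 and 900 for high salt 7 and 45 min, low salt 7 and 45 min, time at high salt, high against low at 7 and 45 min, time at low salt, and interaction. Within the second round they were 2005 (high salt 7 min), 218 and 211 (low salt).

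With the replicate letter as a block over treated arrays the counts were 949 (time at high salt), 550 and 715 (high against low at 7 and 45 min) and 175 (interaction), against 683, 379, 536 and 60 without a block. The letters of low salt gave a correlation of only 0.0904 between times, and between NaCl levels 0.110 and -0.101 at 7 min, so there a pairing was not taken to hold. The value of 0.0904 lies close to the 0.102 of the C arrays of high salt, so this division is not sharp. With 2 arrays in each low-salt group, different letters give -0.0904 between times by construction. Under that block the calls of repA (adjusted p = 0.170), mutL (0.0670) and hutC (0.120) at 7 min of high against low salt were lost, and of repA (0.170), mutL (0.0640), cysS (0.0669) and purF (0.0597) at 45 min, of bchB (0.0780) between the times of high salt, and of 5 interaction probe sets (pstA, appA, rpsB and tsf, 0.0685 to 0.173). Pigment synthesis passed at 45 min of high against low salt under it (median 0.40, adjusted p = 0.000283). At 7 min of high against low salt, 32.1% of changed probe sets rose with no normalization and 33.1% with median centring, against 42.7%. Leaving out 1 array gave 671 to 1519 (high salt 7 min), 1167 to 1368 (high salt 45 min), 0 to 8 (low salt 45 min), 627 to 1175 (time at high salt), 90 to 1114 and 229 to 630 (high against low at 7 and 45 min) and 32 to 387 (interaction). Low salt 7 min and time at low salt stayed at 0, with 253 and 66 at an unadjusted p under 0.05 with limma.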

Other observations

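The gene groups and the low-salt fits here were chosen after their values had been seen. No list test was run on these groups, and 655 of all 5352 probe sets rose at 45 min of high salt. Of the MEP route to isoprenoids, 5 genes picked by their values rose there: dxr by 1.65, gcpE by 1.01 (adjusted p = 8.33e-05), LytB by 0.90, ispD by 0.89 and Dxs by 0.73. None of these passed at 7 min. Of the phosphate uptake genes, pstC (1.31), pstA (1.20), pstB (1.19) and phoU (0.97) rose at 45 min, while pstB had fallen at 7 min (-0.72, adjusted p = 0.004) and phoB did not pass at either time. The xylose binding gene xylF rose by 1.10 at 7 min and fell by 1.16 at 45 min. Glutamate synthase gltB fell by 1.67 at 45 min.

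Without the third round, 11 of 19 flagellum genes fell at 45 min of low salt, among them flgB (-1.41), flgG (-1.31), flhA (-1.30) and flgC (-1.24). The largest changes at 45 min of high salt lay in probe sets without a symbol: numbers 4008 (5.63 ± 0.41) and 4007 (5.25) rose, and 945 (-4.60) and 1810 (-4.45) fell.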
